A study of Rattus norvegicus with 18 samples.

How the data were processed

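RNA was measured on 18 Affymetrix-type rat expression arrays, 9 from heart allografts and 9 from T cells. Each array is 1 combination of tissue, treatment (none, cyclosporine, or cyclosporine plus an allochimeric peptide) and day after transplantation (1, 3 or 7). Biotin-labelled cRNA was made from total RNA with an Enzo amplification and labelling kit, per the labels' protocols. The authors deposited 1 linear intensity per probe set and array. The software and the normalization behind these intensities are not given in the sources used here. Upper quartiles ran from 742 to 758 in heart and from 728 to 739 in T cells, so the arrays had been brought to a similar scale before deposit. Of all intensities, 771 (0.138%) lay below 0, so some background had been subtracted. The number of arrays limits the precision of every value.

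Intensities below 0 were set to 0 and all were used as log2(intensity + 16), with no further scaling. A log2 difference on this scale understates the change of weakly expressed genes. The table holds 31099 probe sets. The 57 control probe sets were left out. Of the other 31042, 20826 have 1 gene symbol in the platform annotation, 436 have several and 9780 have none there. Entrez identifiers of 20764 of these 20826 matched the reference gene table, and 0 symbols were changed by it. No gene was named from a probe set with several symbols. A gene with several probe sets is represented by the 1 with the highest mean over the 18 arrays, 14217 genes in all. A probe set was tested where it lay above the 40th percentile of its array in at least 3 arrays of the fit.

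Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with a trend of the spread in mean signal and Benjamini-Hochberg adjustment over the probe sets tested, at an adjusted p below 0.05. For each tissue, treatment and day (as a factor) were fitted to its 9 arrays, with 4 residual degrees of freedom before moderation. A treatment difference is then the mean of 3 same-day differences, and a day difference the mean of 3 same-treatment differences. No combination has a second array, so the residual spread is how unevenly the treatments differ over the days, plus array noise. The labels do not say which arrays share an animal or whether RNA was pooled, so a p-value measures the spread between these samples, which may be technical. T cells were compared with heart over all 18 arrays with 12 residual degrees of freedom. Whether a treatment difference depends on the tissue was tested as an interaction with 8. Whether it changes with log2(day) in heart was tested with 3. The arrays of 1 day were compared without a test.

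The 24 gene lists for cell types and pathways hold 473 entries, of which 413 have a probe set. Lists with at least 5 tested members were tested with camera of limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation. For T cells against hearts the estimated correlation called 1 list where the preset called 12, and in each other comparison it called 0. Its recovery of known shifts was not simulated, so a high adjusted p from it does not show that a list was unchanged. For each list, the number of members past the threshold is given over all probe sets tested and adjusted over the list alone. For a single day, the median of a list was placed among 10000 random lists of the same size matched on mean expression, as a description of these arrays. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, per comparison and direction, the 12 largest differences among genes past the threshold with the same sign in all 3 differences. Where fewer than 5 pass, it takes the 10 genes with the largest smallest-of-3 difference, as values that did not pass. It adds list members past the threshold, up to 4 members per list by size, and for each single-day comparison the 8 largest differences.

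The tests were tested on simulated data with the fitted day means and spreads and 200 probe sets changed by known amounts, in 5 simulations each. In cyclosporine minus untreated heart, changes of 0.5, 1 and 2 on the log2 scale were recovered in 74.5%, 99.1% and 100% of cases, with 13.2 false calls on average. The same comparison in T cells recovered 32.7%, 93.7% and 99.4%. The slope test in heart recovered 0.302%, 38.4% and 83.4%. A list of proliferation genes shifted by 0.5 was called in 5 of 5 simulations of the heart and of the T cell treatment comparison. Over these simulations, lists without a shift were called 4 times in heart and 2 times in T cells at the preset correlation. The simulated noise was independent between probe sets, and each simulated treatment change was the same on all 3 days. Changes that differ between days and lists of correlated genes were not simulated, so these rates do not carry over to them.

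The alternatives were quantile normalization over all arrays or within a tissue, centring on array medians, other pseudocounts, other signal filters, other settings of the spread, 1 probe set per gene, a fit over all 18 arrays, other day terms, and leaving out each day or treatment in turn. Leaving out the untreated day 1 T cell array was added after the data were seen. The closing part on processing gives their effect.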

Results

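Gene expression was measured in a rat model of heart transplantation. Hearts of Wistar Furth donors were grafted into the abdomen of ACI recipients, which differ from the donors in the class I transplantation antigen RT1.A, per the protocols. All samples, T cells included, carry the strain label Wistar Furth, so the strain that the T cells came from is not settled here, nor is the organ. The 3 groups were untreated recipients, recipients given oral cyclosporine (a calcineurin inhibitor that blocks T cell activation) at 10 mg/kg/day on days 0 to 2, and recipients given this course plus 1 mg/kg of an allochimeric class I peptide into the portal vein at transplantation. The cyclosporine course is described as below the therapeutic dose. The heart allograft and T cells were profiled on days 1, 3 and 7 with 1 array each, 18 arrays in all. The untreated group was meant as the baseline for both treatments. Median signal ran from 210 to 231 in the heart arrays and from 195 to 210 in the T cell arrays. Differences below are log2 differences with the SE of the fit, whose spread is pooled over all its arrays. Each treatment or day difference is a mean of 3 differences between arrays and each T cell minus heart difference a mean of 9, unless a single day is named.

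T cells and hearts were first compared to check the tissue labels. Heart muscle transcripts were far lower in T cells, with Myh7 (beta myosin heavy chain) at -8.99 ± 0.15, Tnnt2 (cardiac troponin T) at -8.62 ± 0.11 and Myl3 at -8.18 ± 0.06. All 24 contractile genes were lower, with a median of -6.75 (adjusted p = 0.0364 with an estimated correlation). T cell transcripts were higher, with Cd3d, a chain of the T cell receptor complex, at 5.05 ± 0.58, Trat1 at 4.98 ± 0.28 and 16 of 17 T cell genes higher and 1 lower (adjusted p = 0.602 with an estimated correlation). The T cell samples also carried B cell transcripts, with Cd79b of the B cell receptor at 5.54 ± 0.33, Cr2 at 5.17 ± 0.27 and Ms4a1, which encodes CD20, at 4.81 ± 0.28. Of 12 B and plasma cell genes, 11 were higher and 1 lower in T cells (adjusted p = 0.507 with an estimated correlation), and the same counts were found adjusted over the list alone. The gene highest over hearts was Cd5l, which encodes a protein secreted by macrophages, at 6.15 ± 0.18. In total, 10692 probe sets were higher and 7929 lower in T cells of 22318 tested. The median of all probe sets was itself shifted by 0.12 as deposited, by 0.18 with quantile normalization over all arrays, by 0.12 with it within each tissue and by 0.23 with centring on array medians, and the differences above are larger than any of these shifts.

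The time course in the allografts asked how the graft changed after transplantation. By day 3, genes of matrix, dividing cells and antigen presentation were higher than on day 1 in all 3 groups. Tnn (tenascin N) rose by 5.25 ± 0.29, Cthrc1 by 3.28 ± 0.23 and P4ha3, a collagen prolyl hydroxylase subunit, by 2.47 ± 0.19. Of the extracellular matrix and fibrosis genes, 18 of 24 rose and 0 fell, among them Col1a1 (1.53 ± 0.18), Postn (1.38 ± 0.18) and Lox (1.20 ± 0.09). All 12 MHC class II genes rose, with Cd74, the invariant chain, at 1.13 ± 0.12, as did 17 of 21 macrophage and monocyte genes, with Cd68 at 1.12 ± 0.08 and Cd163 at 1.13 ± 0.14. Of 27 proliferation genes, 19 rose, for example Plk1 (1.73 ± 0.16) and Bub1b (1.84 ± 0.30). These 4 lists were called at the preset correlation and not otherwise (adjusted p = 0.716 with an estimated correlation for each). Of the T cell genes only 2 of 16 rose, Thy1 (1.54 ± 0.12) and Cd4 (1.45 ± 0.20), which other cells also express. Of the cytotoxic genes 2 of 13 rose, Gzma (0.51 ± 0.09) and Gzmb (0.59 ± 0.13), the latter not called without the cyclosporine arrays (0.55) or without those with the peptide added (0.71). Mitochondrial genes moved down, with 23 of 30 oxidative phosphorylation genes lower (median -0.28, adjusted p = 0.716 with an estimated correlation) and Cox7a1 at -1.45 ± 0.16. The stretch-responsive Ankrd2, which is not on that list, was at -1.77 ± 0.15. Adjusted over the list alone, the counts were 19 of 24 matrix, 12 of 12 MHC class II, 19 of 21 macrophage and 19 of 27 proliferation genes higher and 25 of 30 oxidative phosphorylation genes lower. In all, 2878 probe sets were higher and 2540 lower of 19734, and centring on array medians turned this split to 2085 higher and 3835 lower. Without the arrays of 1 treatment, the total of 5418 became 3482 (untreated left out), 1990 (cyclosporine left out) or 1587 (cyclosporine plus peptide left out).

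By day 7 the grafts of all 3 groups carried a strong T cell and interferon gamma profile. All 16 T cell genes rose, with a median of 2.97, among them Cd3d (5.03 ± 0.34) and Cd8b (4.03 ± 0.13). All 13 cytotoxic effector genes rose (median 3.09), among them Gzma (4.61 ± 0.09), Gzmb (3.70 ± 0.13) and Faslg (2.68 ± 0.13), which encode granzymes and the Fas ligand. Of 21 interferon gamma response genes, 20 rose (median 2.71), led by Ubd (6.35 ± 0.42), Ido1, a tryptophan-degrading enzyme (5.36 ± 0.15), and Ciita, the master regulator of MHC class II, which is itself on that list (4.38 ± 0.25). Ifng itself rose by 2.56 ± 0.14. All 12 MHC class II genes rose (RT1-Db1 3.60 ± 0.15), as did 15 of 17 type I interferon genes (Isg15 2.50 ± 0.16), 20 of 21 macrophage and monocyte genes (C1qb 2.48 ± 0.08) and 6 of 8 dendritic cell genes (Clec9a 3.59 ± 0.20). Each of these 7 lists was called at the preset correlation but had adjusted p = 0.350 with an estimated correlation. This was the lowest value that the estimated correlation gave for any list in this comparison. All 27 proliferation genes rose (Ccnb2 2.44 ± 0.22), 7 of 9 B and plasma cell genes rose and 1 fell, and of the genes that depend on calcineurin and NFAT, which cyclosporine blocks, 11 of 16 rose and 1 fell (Tnfrsf9 3.76 ± 0.31). For these 3 lists the value was adjusted p = 0.458 with an estimated correlation.

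Over the same interval the metabolic genes of heart muscle and the endothelial genes fell. All 24 fatty acid oxidation genes fell, with a median of -1.21, among them Hadh (-2.51 ± 0.11), Acaa2 (-2.00 ± 0.05) and Pdk4 (-2.90 ± 0.14), which encodes an inhibitor of pyruvate oxidation. All 13 endothelial genes fell (median -0.76), for example Vwf (-2.10 ± 0.11) and the junction gene Cldn5 (-1.86 ± 0.11). Both lists had adjusted p = 0.350 with an estimated correlation. Of 30 oxidative phosphorylation genes 29 fell, with a median of -0.56 (adjusted p = 0.458 with an estimated correlation). The contractile list changed less, with 13 of 24 genes lower, 3 higher and a median of -0.23 (adjusted p = 0.496 with an estimated correlation), and Myh6 (alpha myosin heavy chain) was at -1.34 ± 0.17. Of 8 neutrophil genes 5 fell, among them S100a9 (-2.56 ± 0.31) and Il1r2 (-2.57 ± 0.25) (adjusted p = 0.515 with an estimated correlation). Hypoxia and glycolysis genes rose in 12 of 21 cases and fell in 1, with Pfkp at 1.47 ± 0.08 (adjusted p = 0.536 with an estimated correlation).

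The remaining lists were mixed at day 7. Of 22 acute inflammatory genes 13 rose and 5 fell, with Il10 at 2.56 ± 0.26 and Cxcl2, a neutrophil chemoattractant, at -3.12 ± 0.32. Of 24 matrix genes 13 rose and 4 fell, of 9 regulatory and inhibitory T cell genes 5 rose and 2 fell, and of 7 naive T cell genes 3 rose and 1 fell. Of 17 heat shock genes 4 rose and 8 fell, of 11 smooth muscle genes 2 rose and 4 fell, and of 6 erythroid genes 1 rose. Of 14 circadian clock genes 7 fell and 0 rose, for example Nr1d1 (-1.03 ± 0.17) and Nr1d2 (-1.01 ± 0.11). Adjusted over the list alone, the counts at day 7 were the same, except for 21 interferon gamma and 12 calcineurin and NFAT genes higher, 6 acute inflammatory genes lower, 0 erythroid genes higher and 1 smooth muscle gene higher. In all, 6100 probe sets were higher and 6673 lower of 19734 tested. The ratio of the 3' to the 5' actin probe sets, a measure of RNA integrity, moved with the day as well, from between 1.84 and 2.44 on day 1 to between 1.41 and 1.43 on day 7. The same ratio of the GAPDH probe sets did not move with it, at 1.495 to 1.574 on day 1 and 1.513 to 1.542 on day 7. A lower ratio means less loss of signal at the 5' end, so the fall of the actin ratio is no sign of poorer RNA on day 7.

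**Figure D1:**
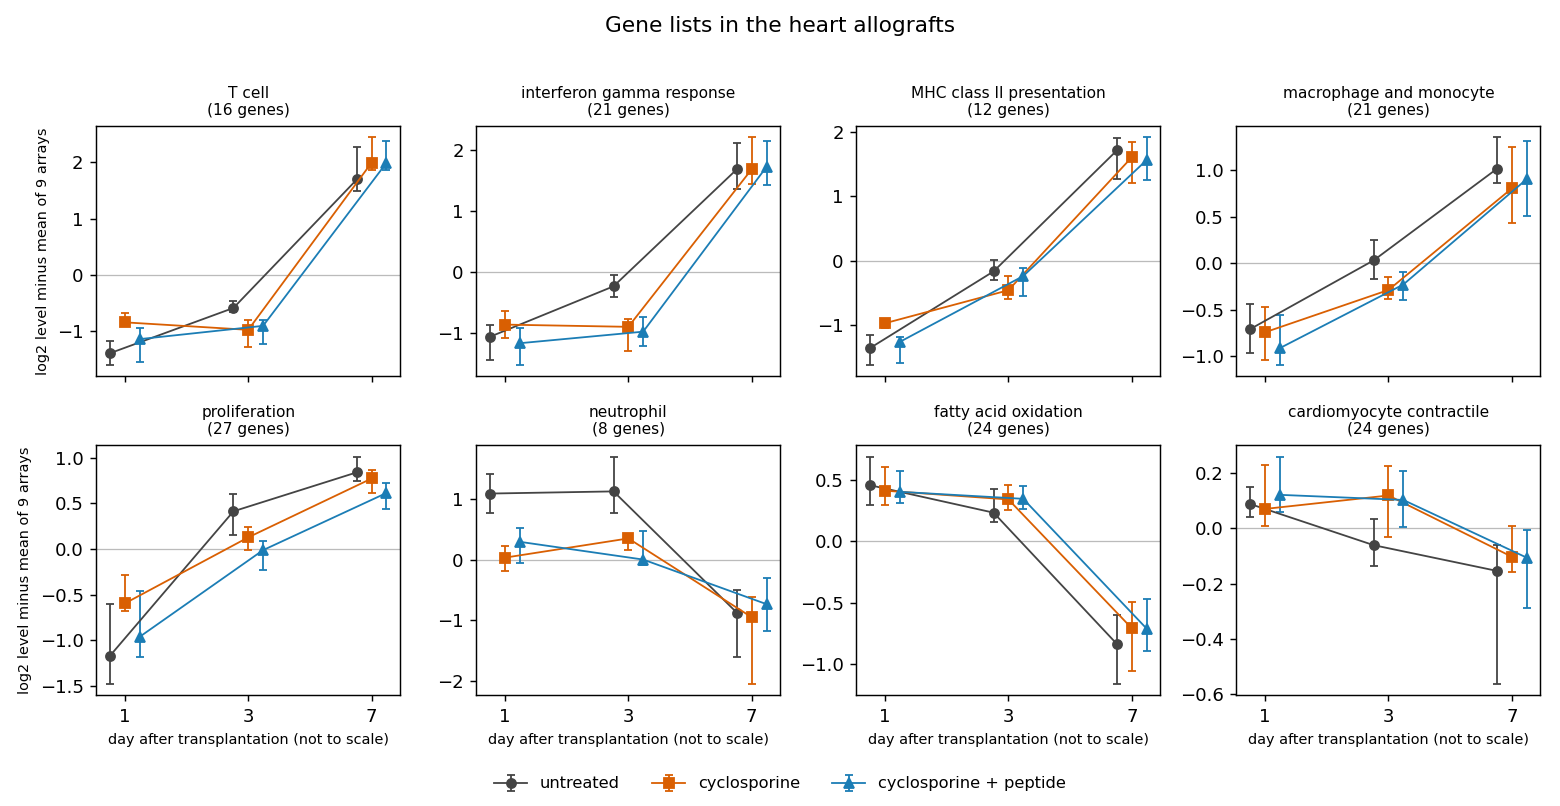
Median log2 level of the members of 8 gene lists in the 9 heart allograft arrays, relative to each gene's mean over these arrays, by day after transplantation (1, 3 and 7, not to scale), with bars from the lower to the upper quartile of the members and 1 array per point. The vertical scales differ between panels; the T cell list has a median day 7 minus day 1 difference of 2.97 and the fatty acid oxidation list of -1.21, against -0.23 for the contractile list.

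Cyclosporine was compared with no treatment in the allografts to ask what the short course changed. Most genes of the acute inflammatory and neutrophil lists were lower with cyclosporine, as values that did not pass the test, and the genes named next differed in the same direction on each of the 3 days. Saa3 (serum amyloid A) was at -1.68 ± 0.52, Hp (haptoglobin) at -1.08 ± 0.33, the cytokine gene Il6 at -0.88 ± 0.13, the heat shock gene Hspa1a at -0.98 ± 0.28 and the transglutaminase gene Tgm1 at -1.02 ± 0.15. Higher values were those of Col6a6 (1.01 ± 0.31), the clock-related transcription factor gene Hlf (0.72 ± 0.17) and Mtnap1 (0.71 ± 0.09). All 8 neutrophil genes were lower, with a median of -0.79 (-1.05, -0.84 and -0.21 on days 1, 3 and 7) and S100a8 at -1.07 ± 0.23, and 19 of 22 acute inflammatory genes were lower, with Ccl4 at -0.69 ± 0.12. All 30 oxidative phosphorylation genes were higher, by a median of 0.11 (on day 1 alone -0.03), and Myh6 was at 0.77 ± 0.17. The 3' to 5' actin ratio was also higher with cyclosporine than without treatment on day 1 (2.27 against 1.84) and day 3 (1.87 against 1.64), and 1.41 in both on day 7, whereas the GAPDH ratio was 1.495 against 1.504 on day 1, 1.506 against 1.649 on day 3 and 1.542 against 1.539 on day 7. These 3 lists were called at the preset correlation but not otherwise (adjusted p = 0.603 with an estimated correlation for each). With limma, 0 of 19734 probe sets passed, and 2287 had an unadjusted p below 0.05 where 987 are expected by chance. Adjusted over the list alone, 5 of 8 neutrophil genes, 4 of 22 acute inflammatory genes, 4 of 21 hypoxia genes, 3 of 17 heat shock genes and 2 of 21 macrophage genes were lower and 3 of 24 contractile genes higher, and no other list had more than 1. Without the day 7 arrays 4 probe sets were called, all lower, and S100a8 was at -1.34.

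Cyclosporine plus peptide was compared with the same untreated arrays, so its values are not independent of those for cyclosporine. Lower on each of the 3 days were Slc47a1 (-1.34 ± 0.25), Tgm1 (-0.96 ± 0.15), Prag1 (-0.75 ± 0.12), the acute phase gene Orm1 (-0.67 ± 0.20) and the folate carrier gene Slc19a1 (-0.61 ± 0.07). Higher were Col6a6 (0.96 ± 0.31), Doc2g (0.82 ± 0.27), Mapt (0.64 ± 0.14) and Ky (0.53 ± 0.11). All 30 oxidative phosphorylation genes were again higher, by a median of 0.10, all 8 neutrophil genes were lower, by a median of -0.49 (-0.88, -1.01 and 0.19 on days 1, 3 and 7), and Myh6 was at 0.78 ± 0.17 (adjusted p = 0.761 with an estimated correlation for both lists). The 3' to 5' actin ratio with the peptide added was 2.44, 1.82 and 1.43 on days 1, 3 and 7, against 1.84, 1.64 and 1.41 without treatment, and the GAPDH ratio was 1.574, 1.625 and 1.513 against 1.504, 1.649 and 1.539. Of 27 proliferation genes 26 were lower, with Aurka, a mitotic kinase gene, at -0.63 ± 0.11 (adjusted p = 0.763 with an estimated correlation). The list was higher on day 1 (median 0.17) and lower on days 3 and 7 (-0.46 and -0.26). None passed: limma called 0 of 19734 probe sets, with 3157 at an unadjusted p below 0.05. Adjusted over the list alone, 4 acute inflammatory, 3 macrophage, 1 neutrophil and 1 proliferation gene were lower and 2 contractile genes higher, and no other list had more than 1. Without the day 7 arrays 1 probe set was called.

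The peptide was then compared on top of cyclosporine, where the described treatments differ by its injection into the portal vein. No injection without peptide is described for the cyclosporine group, so the peptide and the injection cannot be told apart. All 27 proliferation genes were lower with the peptide, by a median of -0.22, with Aurka at -0.50 ± 0.11 and Bub1b at -0.68 ± 0.30, and this list was called at the preset correlation only (adjusted p = 0.873 with an estimated correlation). Other lower values were those of Pold1, a DNA polymerase subunit gene, at -0.56 ± 0.10, Rad17 at -0.53 ± 0.09 and Ube2t at -0.43 ± 0.21. Higher values were those of Pcp4 (0.63 ± 0.25), Foxc2 (0.39 ± 0.10), Slc12a3 (0.38 ± 0.10) and Inhba (0.31 ± 0.17). Of 11 smooth muscle and pericyte genes 10 were higher, with a median of 0.21 and Tagln at 0.27 ± 0.14 (adjusted p = 0.873 with an estimated correlation). With limma 0 of 19734 probe sets passed, 954 had an unadjusted p below 0.05 where 987 are expected, and 0 members passed adjusted over the list alone in any of the 24 lists.

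Single days were compared without a test, 1 array against 1 array. On day 1 the cyclosporine graft had more of the lipid-related Scd (964 against 61.5 in signal) and Adipoq (576 against 177) than the untreated graft, and less Saa3 (96.3 against 338). The T cell list was higher with cyclosporine on day 1 (median 0.64) and lower on day 3 (-0.35). On day 3 several immune lists were lower in both treated grafts than in the untreated graft, while the type I interferon list was at 0.36 with cyclosporine and -0.02 with the peptide added. The oxidative phosphorylation list (0.22 and 0.18) and the contractile list (0.16 and 0.15) were higher in both treated grafts. The interferon gamma list was at -0.65 with cyclosporine and at -0.72 with the peptide added, each at percentile 0 of the matched random lists, and the calcineurin and NFAT list at -0.63 and -0.44. The neutrophil list was at -0.84 and -1.01 and the acute inflammatory list at -0.58 and -0.55. Single genes on day 3 included Saa3 (-2.48 and -2.96), Fos (-1.89 with cyclosporine) and Lcn2 (-1.95 with the peptide added). On day 7 the interferon gamma list lay at 0.00 and 0.04 against the untreated graft, whereas the hypoxia and glycolysis list was lower (-0.39 and -0.42). Arg1, the arginase of alternatively activated macrophages, was at -2.65 and -2.62, and Aldh1a1, a retinaldehyde dehydrogenase gene, at 2.19 and 2.77.

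**Figure D2:**
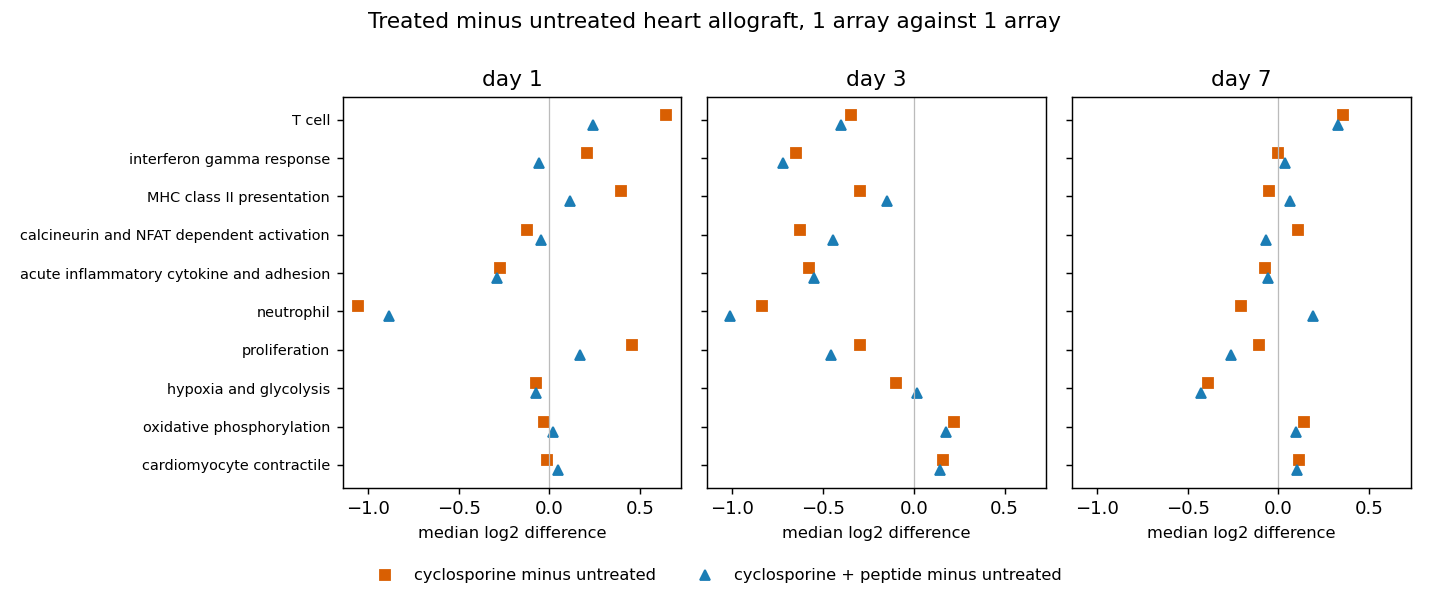
Median log2 difference of 10 gene lists between a treated and the untreated heart allograft on days 1, 3 and 7, each point from 1 array against 1 array, for cyclosporine (squares) and cyclosporine plus peptide (triangles). On day 3 both points of the interferon gamma list lie to the left of 0, at -0.65 and -0.72, and on day 7 they lie at 0.00 and 0.04.

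Whether the treatment differences in the grafts grew or shrank over time was tested as a slope on log2(day). For cyclosporine against no treatment, limma called 0 of 19734 probe sets (101 at an unadjusted p below 0.05, where 987 are expected). For cyclosporine plus peptide it called 0 against no treatment and 0 against cyclosporine (99 and 20 at an unadjusted p below 0.05). Of the neutrophil genes, 1 of 8 passed adjusted over the list alone for cyclosporine plus peptide against no treatment, with a list median of 0.35 (adjusted p = 0.588 with an estimated correlation). The test had 3 residual degrees of freedom and no day factor. A day course shared by the groups that is not linear in log2(day) therefore adds to its residual spread. The counts below those expected and the 0 calls thus do not show that treatment differences were steady over time.

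In the T cells, the day was compared to ask how the cells changed after transplantation. By day 7 cytotoxic and cell cycle genes were higher than on day 1. Gzma rose by 1.52 ± 0.18, Gzmb by 0.93 ± 0.09 and Faslg by 1.00 ± 0.15, and 5 of 14 cytotoxic effector genes rose. Ccnb2 (1.18 ± 0.13), Plk1 (1.08 ± 0.13) and Tyms (1.04 ± 0.13) were among the 10 of 27 proliferation genes that rose. The chemokine gene Ccl4 rose by 1.01 ± 0.09, Ccl3 by 0.75 ± 0.11 and the glucocorticoid-induced Tsc22d3 by 1.03 ± 0.08. Among the genes that fell were Cd22, a B cell receptor inhibitor (-1.14 ± 0.17), Lamp3 (-1.45 ± 0.23) and Chka (-1.39 ± 0.21). Of the B and plasma cell genes 1 of 12 fell, and the value of Cr2 was -1.70 ± 0.28 (adjusted p = 0.0503). Markers of other cells differed too, as values that did not pass: all 6 erythroid genes were higher (median 0.42, with -0.42, 0.16 and 2.35 in the untreated, cyclosporine and peptide groups), and without the untreated day 1 array their median was 1.46, with 2 passing adjusted over the list alone. The neutrophil list was at -0.90 and, without that array, at 0.36, with 5 of 6 genes higher and 3 passing adjusted over the list alone, beside medians of 0.56 for the cytotoxic and 0.60 for the proliferation list. The cytotoxic, proliferation and B and plasma cell lists were called at the preset correlation only (adjusted p = 0.691 with an estimated correlation for each). Counted with p adjusted over the list alone, 10 cytotoxic, 23 proliferation and 9 interferon gamma genes were higher and 5 B and plasma cell genes lower, and without the untreated day 1 array these counts were 9, 22, 0 and 2. In all, 85 probe sets were higher and 27 lower of 19454, and centring on array medians gave 131 and 70. Leaving out the arrays of any 1 treatment or of day 3 left 0 calls, and without the untreated day 1 array alone 13 were higher and 3 lower, with 1 cytotoxic and 1 proliferation gene among the calls.

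By day 3 the cell cycle genes of the T cells already lay above day 1, as values that did not pass. Plk1 was at 1.05 ± 0.13, Cdkn3 at 0.90 ± 0.11, Asf1b at 0.89 ± 0.11 and Tyms at 0.82 ± 0.13, and Tnfrsf17, the plasma cell receptor BCMA, at 1.03 ± 0.18. Lower values were those of Cr2 (-1.21 ± 0.28), Chka (-1.13 ± 0.21) and Lamp3 (-0.88 ± 0.23). The proliferation list had a median of 0.64 (adjusted p = 0.743 with an estimated correlation), and adjusted over the list alone 26 of its 27 genes were higher, or 24 without the untreated day 1 array. The erythroid list was at 0.22 and the neutrophil list at -0.93 (adjusted p = 0.743 with an estimated correlation), or 0.94 and 0.15 without that array. With limma 0 of 19454 probe sets passed, with 1617 at an unadjusted p below 0.05.

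Cyclosporine against no treatment in the T cells asked which transcripts differed between these groups over the 3 days. The course ended on day 2, so only the day 1 samples were taken during it. The comparison on that day rests on the untreated day 1 array, which differed most from the other T cell arrays. The mean over the 3 days therefore does not isolate the action of the drug while it was given. Cell cycle and myeloid transcripts were lower and cytotoxic ones higher, as values that did not pass over all probe sets. All 27 proliferation genes were lower, by a median of -0.46, with Mki67 at -0.76 ± 0.13 and Bub1 at -0.65 ± 0.12, and adjusted over the list alone 22 were lower, or 18 without the untreated day 1 array. Of 14 cytotoxic genes 13 were higher, with Ncr1 at 0.48 ± 0.15 and Gzmm at 0.45 ± 0.11, and 5 passed adjusted over the list alone, or 0 without that array. The largest lower values were those of the neutrophil defensin genes RatNP-3b (-3.03 ± 0.53) and Np4 (-2.89 ± 0.39), followed by Gstt3 (-2.17 ± 0.27), and the monocyte gene Cd14 was at -1.36 ± 0.40. All 8 neutrophil genes were lower, by a median of -1.67, which was -0.56 over the 6 tested without the untreated day 1 array, and all 20 macrophage genes were lower (median -0.50, or -0.28 without it). These 4 lists were called at the preset correlation only (adjusted p = 0.554 with an estimated correlation for each). Higher values were those of Prdm16 (0.93 ± 0.11), Podxl2 (0.85 ± 0.14) and the T cell surface gene Cd7 (0.63 ± 0.06). With p adjusted over the list alone, 6 macrophage, 5 heat shock and 4 B and plasma cell genes were lower, each 0 without that array, and 2 neutrophil genes, or 3 without it. The calcineurin and NFAT list showed no fall without that array, with a median of 0.04, 9 of 16 genes higher and 7 lower. On day 1 the signal of Ifng was 166 with cyclosporine against 29.5 in the untreated array, whose T cell list lay 0.64 below the other arrays. With limma 0 of 19454 probe sets passed, with 2216 at an unadjusted p below 0.05, and a fit over all 18 arrays called 121, of which 106 were lower.

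Cyclosporine plus peptide against no treatment in the T cells had the lowest p-values of the treatment comparisons. Cd7 was higher by 0.68, 0.70 and 0.71 on the 3 days (0.70 ± 0.06, adjusted p = 0.0812), and Prdm16 (1.03 ± 0.11), Podxl2 (0.93 ± 0.14) and Rnf113a1 (0.77 ± 0.14) were also higher. Lower values were those of Gstt3 (-2.05 ± 0.27), Np4 (-2.06 ± 0.39), the complement gene C3 (-1.77 ± 0.58) and the monocyte chemokine receptor gene Ccr2 (-1.10 ± 0.33). All 20 macrophage genes were lower (median -0.46, 5 adjusted over the list alone; -0.18 and 4 without the untreated day 1 array; -1.17, -0.33 and 0.03 on days 1, 3 and 7), and 26 of 27 proliferation genes were lower (median -0.18, 0 adjusted over the list alone). The neutrophil list had a median of -1.19 that turned to 0.22 over the 6 genes tested without that array, with 0.02 on day 3 and -0.03 on day 7. These 3 lists were called at the preset correlation only (adjusted p = 0.583 with an estimated correlation for each). Of 15 heat shock genes 5 were lower and 1 higher adjusted over the list alone, with Hspa5, an endoplasmic reticulum chaperone gene, at -0.57 ± 0.10, and 3 were lower without that array. With limma 0 of 19454 probe sets passed, and 4631 had an unadjusted p below 0.05 where 973 are expected. This count turned on the arrays used: without day 1, 1118 were higher and 1371 lower, and a fit over all 18 arrays called 939 higher and 1210 lower, but without day 3, without day 7 or without the untreated day 1 array alone it was 0. In the fit without day 1, 26 of 27 oxidative phosphorylation genes were higher (median 0.20, 7 called), as were all 6 erythroid genes (0.60, 1 called). In the same fit 26 of 27 proliferation genes were lower (-0.25, 3 called). That fit called 2489 probe sets in all, and whether these lists held more calls than other genes was not tested. It also had fewer residual degrees of freedom than the fit with all 3 days.

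The peptide on top of cyclosporine was also compared in the T cells. Of 27 proliferation genes 26 were higher with the peptide, by a median of 0.26, with Ube2c at 0.43 ± 0.12 and Bub1 at 0.42 ± 0.12, and 12 of 14 cytotoxic genes were lower (median -0.18), with Ncr1 at -0.53 ± 0.15. Both lists were called at the preset correlation only (adjusted p = 0.905 with an estimated correlation). The calcineurin and NFAT list was lower in 14 of 16 genes by a median of -0.08 (adjusted p = 0.557 with an estimated correlation). The neutrophil genes S100a8 (1.27 ± 0.92) and S100a9 (1.24 ± 0.85) were higher on each day, and Klf7 (-0.94 ± 0.16), Cldn3 (-0.70 ± 0.13) and Sp4 (-0.56 ± 0.21) were lower. With limma 0 of 19454 probe sets passed, with 855 at an unadjusted p below 0.05, and 0 members passed adjusted over the list alone in these lists. Without the untreated day 1 array 1 probe set was called, S100a9 was at 1.24, and 4 of the 6 neutrophil genes tested were higher adjusted over the list alone (median 0.74), as were 4 neutrophil and 5 erythroid genes without day 1.

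Day 1 of the untreated group differed most from the other T cell arrays, with a median correlation of 0.973 with them, where the median of this measure over the 9 arrays was 0.984. Its signal was 12964 for S100a8, 17774 for S100a9 and 9423 for the erythroid gene Alas2, against 237, 515 and 2264 with cyclosporine on the same day. The neutrophil list was at -4.07 with cyclosporine and -3.44 with the peptide added against this array, and the erythroid list at -1.62 and -2.73. On day 3 Prss3 was at -2.67 and -3.65 in the treated samples. The type I interferon list was at -0.12 and -0.59 on day 3, and the interferon gamma list at -0.22 and -0.55. On day 7 the mast cell protease genes Mcpt3 (1.16 and 1.37) and Cma1 (1.06 and 1.29) were higher in the treated samples. These values come from 1 array against 1 array.

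**Figure D3:**
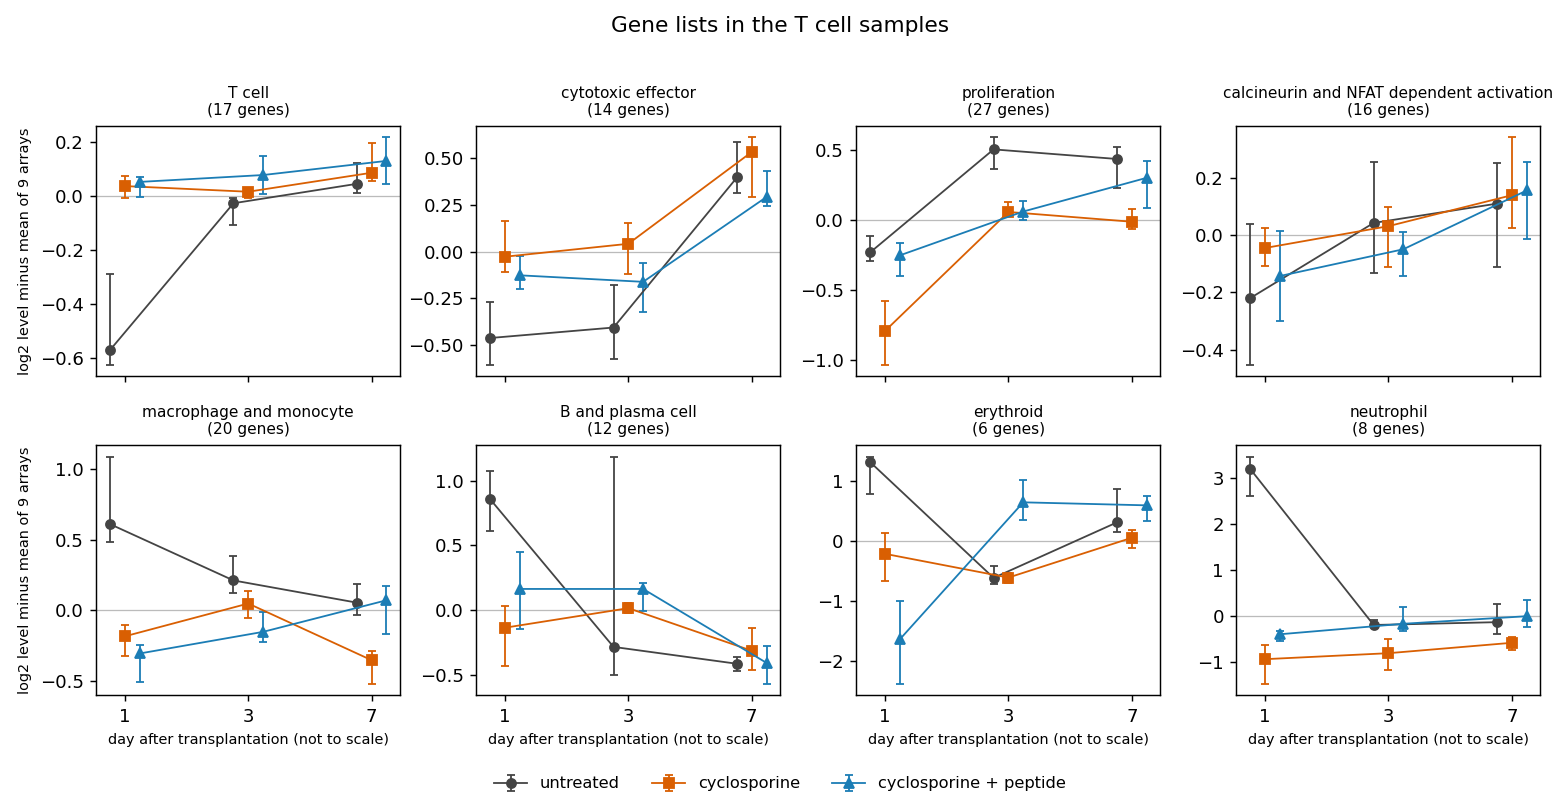
Median log2 level of the members of 8 gene lists in the 9 T cell arrays, relative to each gene's mean over these arrays, by day after transplantation (1, 3 and 7, not to scale), with bars from the lower to the upper quartile of the members and 1 array per point. The vertical scales differ between panels; the untreated day 1 array lies far above the others in the neutrophil list, by 3.60 against the mean of the other 8 arrays, and 0.64 below them in the T cell list.

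Whether a treatment difference depended on the tissue sampled was tested as an interaction. For cyclosporine, 1 of 22318 probe sets passed, a probe set of Mgll, the monoglyceride lipase gene, at -1.30 in T cells and 0.06 in hearts (difference -1.35 ± 0.15, adjusted p = 0.0272). Another probe set, with the higher signal, represents Mgll elsewhere and did not pass (-0.70, adjusted p = 0.382). For cyclosporine plus peptide, 1 passed, that of the nuclear receptor gene Nr2f2, at -1.04 in T cells and 0.08 in hearts (difference -1.12 ± 0.13, adjusted p = 0.0443). Both genes were lower in the treated T cell samples on each of the 3 days, and both were singled out after their values were seen. The T cell samples also held transcripts of other cells, so a difference in cell content was not told apart from a response of T cells. For the peptide on top of cyclosporine, limma called 0 of 22318 (1145 at an unadjusted p below 0.05), and the proliferation list differed between the tissues by a median of 0.47, with 11 of 27 genes higher adjusted over the list alone (adjusted p = 0.755 with an estimated correlation). Without the untreated day 1 T cell array neither was called, with differences of about the same size, at -1.27 ± 0.16 for Mgll (adjusted p = 0.0977) and -1.07 ± 0.14 for Nr2f2 (adjusted p = 0.0533), smaller by less than 1 SE and with a larger SE.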

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

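The tests of explanations for the untreated day 1 T cell array, the fatty acid oxidation genes and the untreated day 3 graft were chosen after the results were seen, except that for saturation of contractile probe sets. The division of the splits of the arrays by matched days or treatments was also made after they were counted.

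By the interaction test, the difference of cyclosporine from no treatment depended on the tissue for a probe set of Mgll (-1.35). That of cyclosporine plus peptide did so for Nr2f2 (-1.12). The erythroid list was lower with cyclosporine than without treatment on all 3 days in T cells (median of days -0.47) and higher on all 3 in hearts (0.05), a gap of -0.52. Without the untreated day 1 T cell array, the fitted median of this list in T cells was 0.04, with 3 genes higher and 3 lower. The proliferation list was lower with the peptide than with cyclosporine alone on all 3 days in hearts (-0.17) and higher on all 3 in T cells (0.21), a gap of 0.38. These list differences were not tested by this route. Of 69 such lists and treatment comparisons 2 went opposite ways throughout, where 2.16 are expected if signs were random and independent.

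The untreated day 1 T cell array stood apart. All 8 tested neutrophil genes (0 are on another list, and 2 lay above the 40th percentile in all other T cell arrays) were highest there among the 9 T cell arrays, with signals of 12964 for S100a8 and 17774 for S100a9 against medians of 622 and 1253 on the other 8. The neutrophil list lay 3.60 above the other arrays, and 3.59 with quantile normalization within the tissue, which argues against scaling. It exceeded the macrophage list by 2.91 where the larger SD of the members was 0.73, which argues against a lower share of T cells alone. Cells of other types in that sample may be the source, a hypothesis in line with the T cell list at -0.64 and with the erythroid (1.49), B and plasma cell (0.96), MHC class II (0.78), macrophage (0.69) and endothelial (0.49) lists above the other arrays; the labels name no sort that would remove them, and with 1 array a response to surgery without cyclosporine stays open and untested.

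In the grafts, fatty acid oxidation genes fell from day 1 to day 7 by more than contractile genes. A lower share of heart muscle cells alone would lower both lists alike, but their medians differed by 0.98, against an SD of 0.52 among the contractile genes. Saturation of the contractile probe sets above the highest fatty acid oxidation signal does not account for all of this, since the 17 contractile genes below that signal still differed by 0.78 (median -0.43). This gap was smaller than the 0.98 of the whole list. Probe sets below that signal may be compressed too, so a part played by saturation is not excluded. A fall in proportion to RNA integrity, as the 3' to 5' actin ratio, is argued against in all 3 arms, since at each arm's rate from day 1 to day 3 the list on day 7 lay further down than proportional, by -0.83 in the arm with the smallest such difference (SD 0.57), and the untreated arm, whose ratio changed least (-0.43), had the lowest median (-1.29). An effect of RNA integrity that is not proportional and a fall within the muscle cells, itself untested, cannot be told apart. This is because the highest actin ratio on day 7 (1.43) lay below the lowest on days 1 and 3 (1.64). A lower actin ratio is, however, no sign of poorer RNA. The GAPDH ratio differed by a mean of only 0.0070 between days 7 and 1, so neither ratio gives evidence of poorer RNA on day 7. The actin ratio also differed between the tissues, at 1.27 to 1.40 in the T cell arrays, so it may not measure RNA integrity alone.

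The untreated day 3 graft stood above both treated grafts in the interferon gamma, T cell and acute inflammatory lists, but not in the type I interferon list, which also rose by day 7 (treated minus untreated 0.36 and -0.02). Scaling is argued against, since with quantile normalization the interferon gamma list still lay 0.67 and 0.72 above them. A graft further along the course from day 1 to day 7 may explain part of it: the 1424 probe sets that rose by over 1 in the treated arms were higher by a median of 0.28 in the untreated day 3 graft (90.1% of them), and the 920 that fell were lower (-0.19, 73.7%). The interferon gamma and T cell lists themselves rose strongly by day 7, so the value for the rising probe sets restates the pattern in part. The shares over all probe sets were not counted. The neutrophil list was higher in the untreated graft on day 1 as well (treated minus untreated -1.05 and -0.88), so it is not particular to day 3, and a later stage is argued against for it, since the untreated day 3 graft lay above all 6 treated grafts of any day by at least 0.84, beyond the SD of 0.45. For the other lists, delay by cyclosporine and a chance difference of the animal cannot be told apart, because the group has 1 array on day 3. A chance difference of the animal on day 3 stays open for the neutrophil list too. The SD of 0.45 is a spread between genes, not between animals.

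Other splits of the arrays were counted for each comparison. For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05, so only the counts follow. Of the other splits, 6 in each comparison break the match of days (or, for day comparisons, of treatments) that the real split has, and 3 keep it, so most of the other counts are no measure of chance for the real split. At an adjusted p below 0.05, the real split of the grafts gave 12773 for day 7 minus day 1 and 5418 for day 3 minus day 1, and that of the T cells 112 for day 7 minus day 1; the highest of the other splits was 0 in each case, and 1 of 10 splits reached the real count. At an unadjusted p below 0.05, cyclosporine minus untreated gave 2287 in grafts (highest other 1657) and 2216 in T cells (1530), and cyclosporine plus peptide minus untreated gave 3157 in grafts (1604) and 4631 in T cells (3355), each reached by 1 of 10. Among the 3 other splits with matched days, the highest were 1283 and 635 for cyclosporine and 1165 and 1943 for cyclosporine plus peptide, in grafts and T cells. The peptide on top of cyclosporine gave 954 in grafts (highest other 1490, 3 of 10 splits as large) and 855 in T cells (3521, 4 of 10, which points to a structure of these samples), and day 3 minus day 1 in T cells gave 1617 (2138, 2 of 10). For the peptide on top of cyclosporine in grafts, the highest other split with matched days gave 427. The counts of 3521 and 2138 themselves came from matched splits. The slopes gave 101, 99 and 20, with 8, 9 and 9 of 10 splits as large and highest others of 4366, 3361 and 5490. All 6 splits with unmatched days were as large, while those with matched days gave at most 170, 242 and 66. In unmatched splits the groups hold different days, and the slope fit has no day factor, so the day course itself can enter the difference. These counts therefore do not measure chance for the slopes.

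For the comparisons with more splits, 100 were counted, the others drawn without matching the days. T cells against hearts gave 18621 calls, more than any other split (highest 15044, 1 of 100). Arrays correlated at 0.935 or more within a tissue and at 0.830 or less between tissues. The outcome was therefore set beforehand, and it checks the tissue labels only. The interaction for cyclosporine gave 1 call, reached by 7 of 100 splits (highest other 3), so chance is not excluded. That for cyclosporine plus peptide gave 1 call, reached by 3 of 100 splits (highest other 12), a share under 0.05, but other splits gave more calls and the alternatives ran from 0 to 75 (75 with the stricter filter and 56 with 1 probe set per gene, each with this call among them), so the count depends on these settings and chance is not firmly excluded. That for the peptide on top of cyclosporine gave 1145 at an unadjusted p below 0.05, reached by 40 of 100 (highest other 3124), so chance is not excluded.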

How the results depend on the processing

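Leaving out the untreated day 1 T cell array was chosen after the results were seen; the other alternatives were planned. Of the counts of calls over the 17 comparisons, 207 stayed within 1.5 times the original and 43 did not. Counts that stayed at 0 are among the 207, and most of the 17 comparisons had 0 calls to begin with. The 207 is therefore no measure of how stable the calls were. Values of named genes kept direction and side of the threshold in 4590 cases, became weaker in 157, stronger in 65 and reversed in 2. List calls held in 1563 cases and were lost in 227, of which 100 were with an estimated correlation. Unless the construction shows it, the cause was not tested.

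Fewer units account for the counts with 1 probe set per gene: 3231 (day 3 minus day 1) and 7377 (day 7 minus day 1) in hearts and 9855 for T cells against hearts. The same setting gave 1 for cyclosporine plus peptide minus untreated in T cells, and 0 and 56 for the tissue interactions of cyclosporine and of cyclosporine plus peptide. These interactions, with 1 call each, gave 0 and 1 with centring on array medians, 3 and 1 with pseudocount 1, 0 and 0 with pseudocount 64, and 0 and 0 without the untreated day 1 T cell array. The second gave 0 with quantile normalization within a tissue, 0 with no filter, 75 with the stricter filter and 2 with no trend. In T cells, day 7 minus day 1 (112) gave 201 with centring, 53 with no trend, 2421 with all 18 arrays in the fit and 16 without the untreated day 1 array. All 18 arrays in the fit also gave 121 (cyclosporine), 2149 (cyclosporine plus peptide) and 1 (peptide on top of cyclosporine) among the T cell treatments, and 16 for day 3 minus day 1. Centring gave 1 for cyclosporine plus peptide in T cells, leaving out the untreated day 1 array gave 1 for the peptide on top of cyclosporine there, and pseudocount 1 gave 1 for cyclosporine in hearts.

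Leaving out a day or a treatment in turn gave 0 to 4 calls (cyclosporine, hearts), 0 to 1 (cyclosporine plus peptide, hearts), 0 to 2489 (cyclosporine plus peptide, T cells), 1587 to 5054 and 9829 to 12584 (days 3 and 7, hearts), 0 to 0 (day 7, T cells, from 112), 16678 to 18354 (T cells against hearts) and 0 to 2 for each of the interactions with 1 call. S100a8 in T cells, cyclosporine plus peptide minus untreated, turned from -1.28 to 0.31 without day 1 (-2.11 to 0.31 over the days left out) and to 0.30 without the untreated day 1 array. A day comparison without its own days and a slope without a day give no value. Genes near the background are limited by the added 16, which shrinks their differences.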

Other observations

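The tests in this part were planned; the choice of what to describe was made after the values were seen.

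The T cell samples held more than T cell transcripts on all days. Cd5l, which macrophages secrete, lay 6.15 above hearts, and Cr2, Ms4a1 and Cd79b of B cells lay 5.17, 4.81 and 5.54 above hearts. Within the T cell arrays, the B and plasma cell list lay lower on day 7 than on day 1 by a median of -0.71 (-0.35 without the untreated day 1 array), while the T cell list differed by 0.23 (0.07 without that array), and Cd22 fell by 1.14. The erythroid list varied between samples, from -1.35 on day 1 to 1.36 on day 3 for the peptide on top of cyclosporine, with Alas2 at -2.50 and 1.92.

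Some genes differed widely between single graft arrays. The keratin gene Krt5 was at -2.62 with cyclosporine on day 3 and at 2.46 for the peptide on top of cyclosporine, and Bpifa1 was at 2.11 with the peptide added on day 3. Scd was at 3.66 with cyclosporine on day 1 and at -2.55 with the peptide added on day 3.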
